A study of Mus musculus with 7 samples.

How the data were processed

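Flag-tagged Ago2, wild type or mutant, was immunoprecipitated with an anti-Flag antibody from mouse embryonic stem cells that lack their own Argonautes, and the bound small RNAs were made into libraries with the NEBNext Small RNA kit and read on a HiSeq 2000, per the labels' protocols. There were 7 libraries, 1 for each of 7 groups: wild-type Ago2, 5 mutants (K566A, Q548A, R792A_C793A, GKT_GKGT and PGKTP_AAAAA) and an empty control. The deposited table holds raw counts, not normalized, for 1078 mature miRNA loci named by miRNA and position. CASAVA 1.8.2, TopHat2 2.0.9 and the mouse build mm9 were used, per the submitters' processing notes. The program that counted reads, the miRNA annotation release and the treatment of reads with several matches are not given in the sources used here. No column belonged to another sample, and 116 rows were at 0 in every library.

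A mature sequence encoded at several loci appeared once per locus. Of 57 such names with counts, 49 had counts at their loci that were equal within 1% or 3 counts. Reads with several matches thus look counted at each locus, though an even split between loci would also give equal counts. Each mature name was therefore counted once, by its highest locus. A further 8 names whose counts equalled those of another name to the same tolerance, with a sum of at least 200, were merged with it. This left 951 miRNAs. A 5p and a 3p locus of 1 name, on 1 chromosome and with starts within 150 nt, formed a hairpin. Strand use in the counting is not given in the sources used here, so the 11 tested miRNAs that overlap another locus are uncertain.

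Totals, counting each sequence once, were 94844631 for wild type, 14914271 for K566A, 94702626 for Q548A, 56067316 for R792A_C793A, 49658186 for GKT_GKGT, 24921821 for PGKTP_AAAAA and 33466 for the empty control. A count of 0 allows up to 3 counts, which is 0.0316 CPM in wild type, 0.201 CPM in K566A and 89.6 CPM in the empty control. Intervals and these limits cover counting error only, since the reads carry no molecular identifiers. With 1 library per group there is no replicate check, and no p-value is given: every comparison is of 2 libraries.

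Counts per 1000000 (CPM) were computed from the deposited counts with the total as library size. A miRNA was tested with a mean of at least 10 CPM over the 6 Ago2 libraries (338 miRNAs), and was called higher or lower when the exact conditional 95% interval of its ratio to wild type lay wholly above 2 or below 0.5. A hairpin was tested with a sum of at least 100 over the 6 Ago2 libraries (402 hairpins). Its major arm was the one with more counts in that sum, and it was called when the exact conditional 95% interval of the minor-to-major odds ratio lay wholly past 2 or 0.5 (Woolf's interval where all 4 counts reached 500). Median changes in log2(minor/major), with a pseudocount of 0.5, carry binomial order-statistic 95% intervals, which describe the hairpins of the 2 libraries. Spearman correlations are across miRNAs, which are not independent replicates. Median-of-ratios scaling would move each log2 ratio by -0.90 in K566A, -0.12 in Q548A, -0.38 in R792A_C793A, 0.23 in GKT_GKGT and 0.58 in PGKTP_AAAAA. Mutants were also set directly against each other, since comparisons with 1 wild-type library share its error.

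The lists were fixed before the data were examined: the miR-290 cluster (to miR-295), the miR-302 cluster (with miR-367), miR-17-92 with paralogs, let-7 with miR-98, miR-15/16, miR-30, miR-183/96/182, miR-200, the Sfmbt2 cluster, the Dlk1-Dio3 cluster, Dicer- or Drosha-independent miRNAs, fibroblast markers, markers of differentiated tissues, and miRNAs by first base from 130 hand-written sequences. Each list's median log2 ratio is given relative to the median of all tested miRNAs, with its percentile among 10000 random lists matched on mean expression in 10 bins. The named-miRNA rule was also fixed: per mutant, the 5 largest rises and 5 largest falls among called miRNAs with a mean of at least 100 CPM, the 5 and 5 hairpins with the largest called changes, the 10 most abundant miRNAs in wild type, up to 4 abundant members of each list, and a list's extremes where its range is given.

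After the data were seen, 59 sequences were added, and the first base of 175 further arms was read from their offset to a known arm in the reference hairpin of the same name and copy number (GENCODE M21). Of the hand-written sequences, 130 of 130 and 58 of 59 were found there. The reference is of build GRCm38, so none of its coordinates were used; positions are mm9 as deposited, and host genes were taken by name. Hairpins whose arms begin with different bases were then read by base, a comparison from which library size cancels only where both arms have counts. Hairpins of which an arm had at most 3 counts in both libraries compared were therefore also left out, a choice made after the values were seen. A fold written as at least takes a 0 as 3 counts in that library and leaves out the counting error of the other counts, which the exact 95% limit beside it includes. The GKT_GKGT and PGKTP_AAAAA results on arms by base, and direct comparisons of them, were chosen after seeing the data.

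Tested on simulated counts with 200 changed miRNAs and 100 changed hairpins, the intervals held the true ratio for 94.7% of 338 miRNAs and 96.8% of 402 hairpins in the comparison simulated for K566A. In that comparison 98.4% of 3-fold miRNA changes and 100% of 8-fold ones were called, 40.5% of 3-fold and 71.0% of 8-fold hairpin changes were called, and 0 of 138 unchanged miRNAs and 0 of 302 unchanged hairpins were called. The simulated counts had counting error only and known library sizes. The simulation therefore covers neither the choice of scaling nor variation between libraries. Alternatives covered scaling (median-of-ratios factors from DESeq2 1.42.0, TMM from edgeR 4.0.16, totals without dominant miRNAs), thresholds, filters, pseudocounts, major-arm choice, subtraction of the empty control, multi-copy hairpins and wild-type counts thinned to each mutant's total or median-of-ratios size. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and ViennaRNA 2.7.2 were used.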

Results

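Small RNAs bound to Flag-tagged Ago2 were counted in 7 libraries from mouse embryonic stem cells without Argonautes of their own. Ago2 is the Argonaute protein that holds 1 strand of a small-RNA duplex as its guide. The series asks, by its title, whether Argonaute itself sets which strand is kept. One library each came from wild-type Ago2, from 5 mutants and from an empty control. K566 and Q548 lie in the MID domain, which holds the 5' end of the guide. The GKT_GKGT and PGKTP_AAAAA labels name changes in the MID loop that faces the guide's first base, and R792A_C793A is a double change in the PIWI domain. The counts do not show the mutations themselves, so the labels could not be checked from them. Depth ran from 14914271 counts (K566A) to 94844631 counts (wild type) in the 6 Ago2 libraries. With 1 library per genotype no difference below has a replicate check, and each compares 2 libraries.

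In wild type, miR-292-5p of the miR-290 cluster, the main miRNA cluster of mouse embryonic stem cells, took 63.7% of counts. Its locus is at chromosome 7, 3219201 to 3219222 (mm9). The next most abundant were miR-293-3p (53721 CPM), miR-292-3p (35894 CPM), miR-433-3p (22567 CPM), miR-294-3p (19962 CPM), miR-99b-5p (14865 CPM), miR-293-5p (12283 CPM), miR-183-5p (10958 CPM), miR-127-3p (9774 CPM) and miR-543-3p (9414 CPM). The miR-292-5p share was 65.3% in Q548A, 57.3% in R792A_C793A, 70.5% in GKT_GKGT and 69.5% in PGKTP_AAAAA, but 21.7% in K566A. The empty control held 33466 counts, 446 times fewer than the smallest Ago2 library, and 65.6% of them were miR-292-5p (Wilson 95% interval 65.1 to 66.1). Its miRNA ranks resembled those of wild type, with a Spearman correlation of 0.85 across miRNAs.

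The GKT_GKGT library differed from wild type by the first base of the miRNA. Among miRNAs of at least 100 CPM, the 5 largest rises were in miRNAs that begin with C: miR-200b-5p (log2 ratio 3.73, 95% interval 3.70 to 3.77), miR-195-3p (3.07), miR-30e-3p (2.86), miR-28-3p (2.67) and miR-200a-5p (2.55). The largest falls included 4 that begin with A, namely miR-409-5p (-2.66), miR-291a-3p (-2.66), miR-296-5p (-2.58) and miR-290-5p (-2.15), beside miR-666-5p (-2.10), whose first base was not assigned. Of 31 tested A-first miRNAs 13 fell and 0 rose, with a median 0.70 log2 units below that of all miRNAs, under each of 10000 matched random lists (percentile 0). Abundant A-first miRNAs were miR-292-3p (-1.36), miR-294-3p (-1.31), miR-293-3p (-0.64) and miR-292-5p (0.15). Of 19 C-first miRNAs 5 rose and 0 fell (percentile 98.6). With median-of-ratios scaling these counts were 9 lower for A-first and 6 higher for C-first miRNAs. Abundant C-first miRNAs were miR-291a-5p at 1.54, miR-99b-5p at 0.12, miR-191-5p at 0.08 and miR-25-3p at -0.45. The 65 U-first miRNAs had a median 0.01 from that of all miRNAs (percentile 46.3). With first bases added after the values were seen, 24 of 47 C-first miRNAs rose, with a median 1.41 above that of all, and 20 of 57 A-first miRNAs fell, with a median 0.55 below it (25 and 16 with median-of-ratios scaling). The 19 G-first miRNAs then had a median 0.41 above that of all, with 2 higher (percentile 99.6), and U-first miRNAs lay at percentile 36.3. The 4 G-first miRNAs fixed before lay at percentile 83.4.

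Arms of 1 hairpin, compared by base after the values were seen, split in GKT_GKGT. In 22 hairpins with 1 C-first and 1 A-first arm, the log2 ratio of the C-first to the A-first arm rose by a median of 2.77 (95% interval 1.67 to 3.52). In miR-181b-1 and miR-181b-2 the C-first arm had at most 1 count in either library. Without these 2 the median was 3.05 (1.86 to 3.52), and 19 of 20 moved that way, with miR-25 (-1.16) the exception. Some hairpins share an arm with another copy; in the 17 with 1 copy the median was 2.51 (1.67 to 3.49). The 5p arm of miR-291a (chromosome 7, 3218933 to 3218990) went from 43.8% of the hairpin's counts in wild type to 93.5%. The 3p arm of miR-28 (chromosome 16, 24827954 to 24828015, in an intron of Lpp) went from 51.0% to 94.97%. Of hairpins chosen after their values were seen, the 3p arm of let-7d went from 57.4% to 91.9% and the 5p arm of miR-199a from 56.5% to 91.8%. C-first arms also gained on U-first arms. The median was 2.20 (1.84 to 2.79) in 51 hairpins, and 2.41 (1.98 to 2.89) in the 44 whose arms both had more than 3 counts in at least 1 of the 2 libraries, with 43 of 44 rising. The other was miR-128-1, whose C-first arm held under 0.1% of wild-type counts. U-first arms lost to G-first arms by a median change of -1.47 (-1.89 to -0.66) in 18 hairpins chosen by the same count limit. For A-first over U-first arms, with that limit, the median change was -0.39 (-0.93 to 0.29) in 39 hairpins. That interval includes 0, so no loss of A-first to U-first arms was detectable within hairpins.

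**Figure D1:**
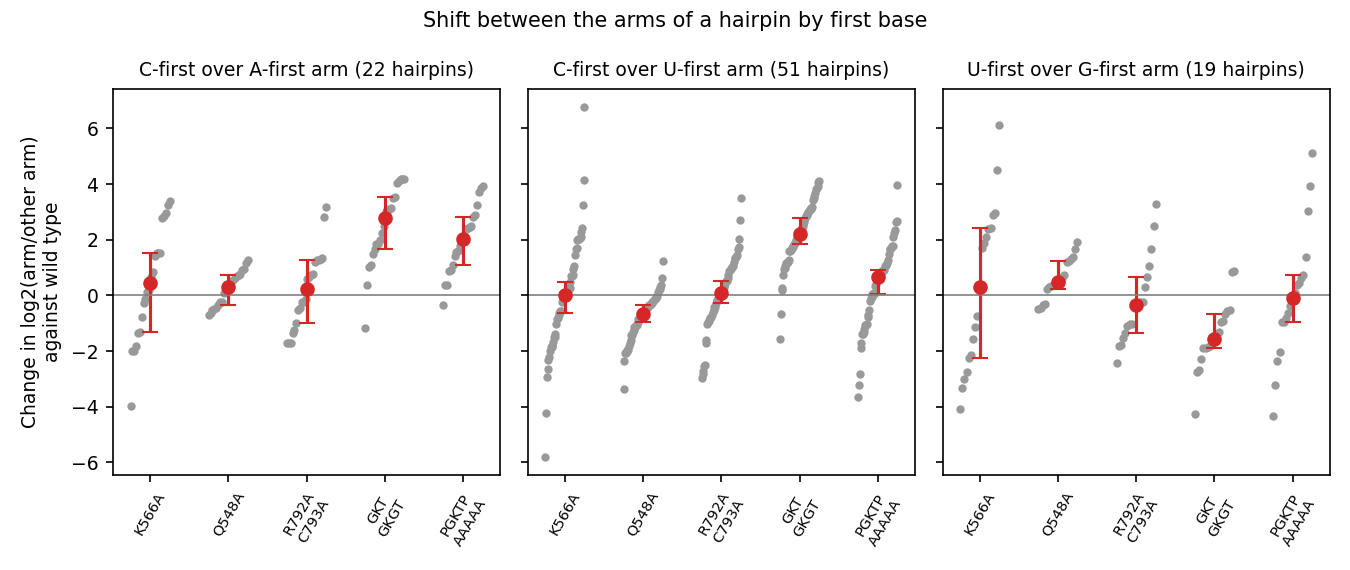
Change against wild type in log2(arm/other arm) for hairpins whose arms begin with different bases, with 1 grey point per hairpin and red points for medians with 95% order-statistic intervals, arms at 0 included with a pseudocount. C-first over A-first arms sit at a median of 2.77 in GKT_GKGT and 2.02 in PGKTP_AAAAA, and between 0.23 and 0.44 in the other 3 mutants.

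In GKT_GKGT the miR-290 cluster list had 6 of 13 members lower and 2 higher (5 and 2 with median-of-ratios scaling), with a median 0.69 below that of all miRNAs (percentile 0.01). Its members with an assigned first base begin with A, except miR-291a-5p. This list therefore shares members with the A-first list and is not separate from the pattern by first base. Of 6 miR-15/16 family members 3 rose (percentile 99.3), namely miR-16-1-3p (3.57), miR-195-3p and miR-15b-3p (2.04), against -0.12 for miR-16-5p. These 3 begin with C and miR-16-5p with U, so this list is not separate from the pattern by first base either. The Dlk1-Dio3 list, from an imprinted cluster on chromosome 12, had a median 0.16 below that of all (percentile 1.72). The remaining 12 lists lay between percentiles 4.38 and 95.1. By hairpin, 70 had a higher and 48 a lower minor-arm share. Besides miR-291a, the largest rises were in miR-1197 (at least 11.1-fold in odds with the wild-type 0 taken as 3 counts, exact 95% limit 7.08-fold), miR-204 (4.27 in log2 odds), miR-218-1 (4.18) and miR-744 (4.10, in an intron of Map2k4). Besides miR-28, the largest falls were in miR-3076 and miR-574, whose minor arms were at 0 in the mutant (at least 6.91-fold and 4.43-fold, exact limits 5.21 and 3.12), miR-129-1 (-4.19) and miR-3067 (-4.17). The median change in log2(minor/major) was 0.40 (0.19 to 0.62), and 0.14 (-0.12 to 0.28) once wild type was thinned to the same total or 0.15 (-0.10 to 0.34) to the median-of-ratios size. The Spearman correlation with wild type was 0.91 across miRNAs. In this library 37 miRNAs rose and 40 fell, and with median-of-ratios scaling 44 rose and 25 fell.

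In PGKTP_AAAAA C-first miRNAs lay high and the Dlk1-Dio3 cluster lay low. Among miRNAs of at least 100 CPM the 5 largest rises were C-first: miR-151-3p (2.58), miR-195-3p (2.16), miR-674-3p (1.98), miR-129-5p (1.60) and miR-200b-5p (1.59). The largest falls among these were miR-666-5p (-4.43), miR-673-3p (-2.99), miR-409-5p (-2.90), miR-323-3p (-2.82) and miR-294-5p (-2.78). Of 58 Dlk1-Dio3 members tested 38 fell and 1 rose, with a median 1.09 below that of all (percentile 0); with median-of-ratios scaling 28 fell and 5 rose. Its abundant members were miR-433-3p (-1.25), miR-543-3p (-2.39), miR-541-5p (-0.57) and miR-127-3p (0.38). The Dlk1-Dio3 list also lay low in K566A (percentile 0), R792A_C793A (0.22) and GKT_GKGT (1.72), but at percentile 24.2 in Q548A. These comparisons share 1 wild-type library, so a trait of that library cannot be told from one of the mutants. A-first miRNAs had 16 of 31 lower (percentile 1) and C-first miRNAs had 3 of 19 higher and 1 lower (percentile 98.2). With median-of-ratios scaling 6 A-first miRNAs fell, and 6 C-first miRNAs rose and 0 fell. In 22 hairpins the ratio of the C-first to the A-first arm rose by 2.02 (1.08 to 2.81). Without the same 2 copies of miR-181b the median was 2.22 (1.42 to 2.81), in 19 of 20, with miR-323 (-0.34) the exception. Against U-first arms it was 0.66 (0.05 to 0.90) in 51 hairpins, but 8 of these had an arm at 3 counts or fewer in both libraries. In the other 43 it was 0.42 (-0.10 to 0.85), an interval that includes 0, and in the 28 of these with 1 copy 0.79 (0.07 to 1.09). A-first over U-first arms, with the same count limit, changed by a median of -1.37 (-1.94 to 0.19) in 38 hairpins, an interval that includes 0. With the added first bases 12 of 47 C-first miRNAs rose and 3 fell (median 0.87 above that of all), 31 of 57 A-first miRNAs fell and 2 rose, and 14 of 19 G-first miRNAs fell and 1 rose (percentile 0.16). U-first miRNAs then had 3 of 95 higher and 19 lower, with a median 0.41 above that of all (percentile 98.8). With median-of-ratios scaling the counts for these added lists were 21 higher and 1 lower for C, 4 and 16 for A, 1 and 7 for G, and 10 and 10 for U. The 4 G-first miRNAs fixed before lay at percentile 22.7. With the count limit on arms, U-first over G-first arms changed by -0.006 (-0.95 to 0.72) in 18 hairpins. The added A-first miRNAs include miR-433-3p and miR-543-3p of the Dlk1-Dio3 list, so these 2 lists are not separate.

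Further lists outside the random range in PGKTP_AAAAA were the miR-15/16 family (1.42 above the median of all, percentile 99.9), the miR-30 family (0.95, percentile 99.4, with miR-30e-3p at 1.20 and miR-30c-2-3p at 0.44), miR-17-92 with paralogs (0.64, percentile 97.7) and the Dicer- or Drosha-independent miRNAs (-1.54, percentile 0.66), of which 6 of 7 fell, and 4 with median-of-ratios scaling. Among these miR-1981-5p was at -2.71, miR-1839-5p at -2.09 and miR-320-3p at -1.28. The other 10 lists lay between percentiles 20.5 and 96.3. Both miR-30 arms named here begin with C, so the miR-30 list is not separate from the pattern by first base. By hairpin 27 rose and 73 fell in minor-arm share. Rises were led by miR-3063 (at least 45.9-fold in odds with 0 taken as 3 counts, exact limit 22.5-fold), miR-3084 (4.39, from 4 and 2 counts in the mutant), miR-3071 (4.14), miR-540 (3.94) and miR-211 (3.88). miR-3071 overlaps another locus and is uncertain. Falls were led by miR-205, miR-138-2, miR-665 and miR-3076, whose minor arms were at 0 in the mutant (at least 5.71-, 5.46-, 4.81- and 3.38-fold, exact limits 4.51, 4.19, 3.70 and 2.502), and miR-145 (-4.61). The median change in log2(minor/major) was 0.04 (-0.32 to 0.24). Against wild type thinned to the same total it was -0.27 (-0.59 to -0.01), and to the median-of-ratios size -0.57 (-0.69 to -0.28), intervals below 0. With a pseudocount of 5 it was 0.49 (0.30 to 0.82), so its direction depends on how low counts are treated. The Spearman correlation with wild type was 0.86. In this library 24 miRNAs rose and 113 fell, and with median-of-ratios scaling 50 rose and 63 fell.

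Set directly against each other, GKT_GKGT exceeded PGKTP_AAAAA in C-first over U-first arms by 2.01 (1.60 to 2.37) in 51 hairpins, and by 2.16 (1.84 to 2.44) in the 44 with both arms above 3 counts in at least 1 library. For C-first over A-first arms the difference was 0.35 (-0.62 to 2.12) in 22 hairpins and 0.74 (-0.62 to 2.12) in 20, intervals that include 0. Against GKT_GKGT the C-first over A-first shift was lower in Q548A by a median difference of -2.69 (-3.66 to -1.04), in R792A_C793A of -2.54 (-3.58 to -1.27) and in K566A of -1.51 (-4.38 to -0.33). Against PGKTP_AAAAA these differences were -1.96 (-2.30 to -1.36), -2.10 (-2.65 to -1.12) and -1.19 (-3.37 to -0.38). With the count limit on arms these 6 medians lay between -3.07 and -1.45, with each interval below 0. The median change in log2(minor/major) was higher in GKT_GKGT than in PGKTP_AAAAA by 0.31 (0.06 to 0.50), which turned to -0.049 (-0.28 to 0.09) with a pseudocount of 5.

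**Figure D2:**
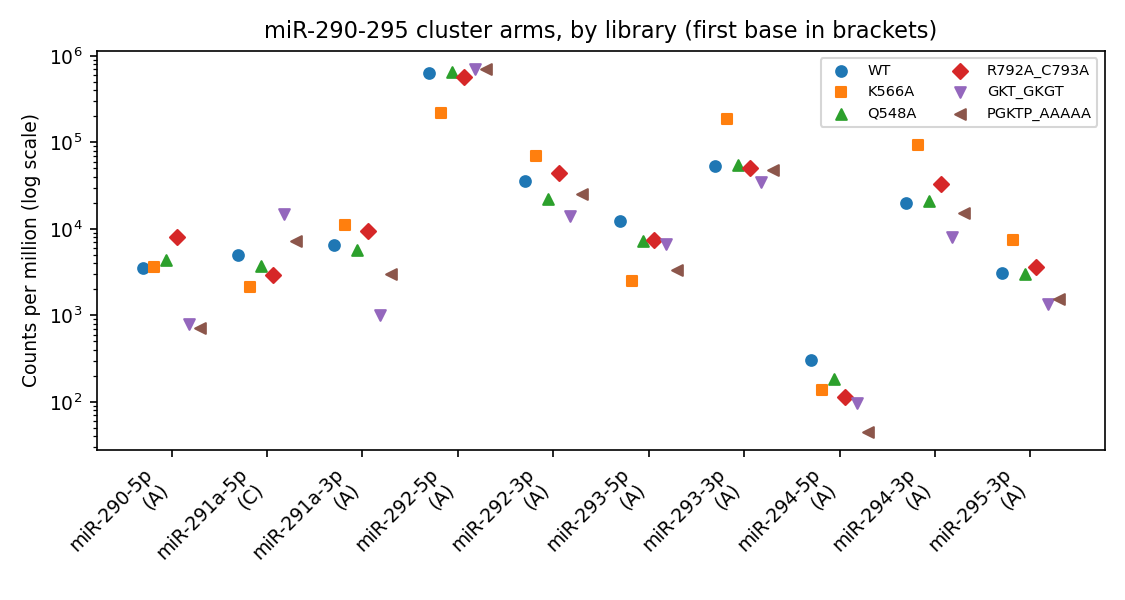
CPM (log axis) of 10 arms of the miR-290 cluster in the 6 Ago2 libraries, with 1 symbol per library and no replicates. miR-291a-3p, which begins with A, was at 1024 CPM in GKT_GKGT against 6469 CPM in wild type, and miR-292-5p was at 217068 CPM in K566A against 636769 CPM in wild type.

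K566A was the library least like wild type, with a Spearman correlation of 0.72 across miRNAs, and it also had the lowest total of the Ago2 libraries. Among miRNAs of at least 100 CPM its largest rises were miR-219-1-3p (4.66), miR-302b-3p (3.41), miR-195-3p (3.40), miR-126-3p (3.23), known from endothelial cells, and miR-21-5p (3.23). The largest falls among these were miR-666-5p (-5.04), miR-323-3p (-4.46), miR-149-5p (-4.40), miR-328-3p (-3.68) and miR-501-3p (-3.61). miR-292-5p fell by 1.55 on the log2 scale, while miR-293-3p (1.78) and miR-294-3p (2.22) had higher CPM. The median of all miRNAs was 0.91, so values of groups are given relative to it. Of 65 U-first miRNAs 48 rose and 4 fell, with a median 1.09 above that of all (percentile 99.965), and 33 rose and 8 fell with median-of-ratios scaling. Among them were miR-127-3p (2.52), miR-148a-3p (2.74) and miR-423-5p (2.33). miR-183-5p, also U-first, was at -0.38. After a linear term for GC content the U-first median lay 0.69 (0.50 to 1.04) above the fitted line, at the edge of the random range. Without that term it lay 1.23 above the mean of the miRNAs with a sequence. Set directly against Q548A, the K566A U-first median lay 0.79 (0.41 to 1.02) above that of all. With the added first bases 6 of 19 G-first miRNAs fell and 3 rose, with a median of -1.799 relative to that of all (percentile 1.16); with median-of-ratios scaling 12 fell and 0 rose, while the 4 G-first miRNAs fixed before lay at percentile 64.4. U-first miRNAs then had 62 of 95 higher and 15 lower (0.90, percentile 99.965), or 42 and 19 with that scaling, and A-first and C-first miRNAs lay at percentiles 22.3 and 62.9.

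Among families in K566A, miR-302 cluster members (miR-302a-3p 3.40, miR-302b-3p and miR-302d-3p 2.89) had a median 2.497 above that of all (percentile 99.7, 3 miRNAs). These 3 begin with U, so this list is not separate from the pattern by first base. Of 24 members of miR-17-92 and its paralogs 16 rose and 1 fell (percentile 99.2; 13 and 3 with median-of-ratios scaling), with miR-25-3p at 3.02, miR-363-3p at 2.45 and miR-92b-3p at -1.31. The miR-15/16 family (1.67, percentile 98.3) had 5 of 6 higher. Markers of differentiated tissues (1.35, percentile 98.8) had 6 of 8 higher, or 5 with that scaling, including miR-9-5p (2.33) and miR-128-3p (2.66). Both miRNAs named here begin with U, so this list is not separate from that pattern either. The Dlk1-Dio3 cluster moved in both directions, with 12 of 58 higher and 26 lower (10 and 31 with that scaling), and its median lay 1.66 below that of all (percentile 0); miR-433-3p (-1.14) and miR-543-3p (-1.38) stood against miR-541-5p (1.70). The other 11 lists lay between percentiles 5.12 and 87.7. These include let-7 with miR-98, where 8 of 9 rose and 4 with median-of-ratios scaling (let-7a-5p 2.18, let-7f-5p 2.497), and fibroblast markers, where 10 of 11 rose and 6 with that scaling (miR-143-3p 1.996, miR-196a-5p 2.78). The miRNAs named for let-7 and the fibroblast markers begin with U as well.

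Within hairpins of K566A, no gain of U-first arms was detectable: with the count limit on arms the median change was -0.099 (-0.83 to 0.70) for C-first over U-first arms, -0.40 (-1.27 to 0.75) for A-first over U-first arms and 1.006 (-2.13 to 2.41) for U-first over G-first arms. By hairpin, K566A had 77 with a higher and 75 with a lower minor-arm share. The 3p arm of miR-744 rose from 0.0798% to 8.12%. The other large rises rest on few counts: miR-344d-2 (at least 102-fold in odds with 0 taken as 3 counts, exact limit 63.4-fold), miR-598 (7.62, 95% interval 4.26 to 11.64), miR-3077 (7.14) and miR-471 (at least 17.5-fold, exact limit 11.98). The 5p arm of miR-145 fell from 76.6% to 0.110% (2 counts against 1811). miR-877, in an intron of Abcf1, changed by -6.12, and the minor arms of miR-34c, miR-302b and let-7i were at 0 (at least 22.8-, 17.3- and 9.22-fold lower, exact limits 17.9, 13.2 and 7.04). The median change in log2(minor/major) was 0.27 (0.04 to 0.69), but -0.19 (-0.44 to 0.19) with wild type thinned to the K566A total. Thinned instead to the median-of-ratios size, since miR-292-5p makes totals and typical depth differ, it was -0.076 (-0.32 to 0.34), so a rise was not detectable against either. In this library 160 miRNAs rose and 66 fell, and with median-of-ratios scaling 105 rose and 107 fell.

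**Figure D3:**
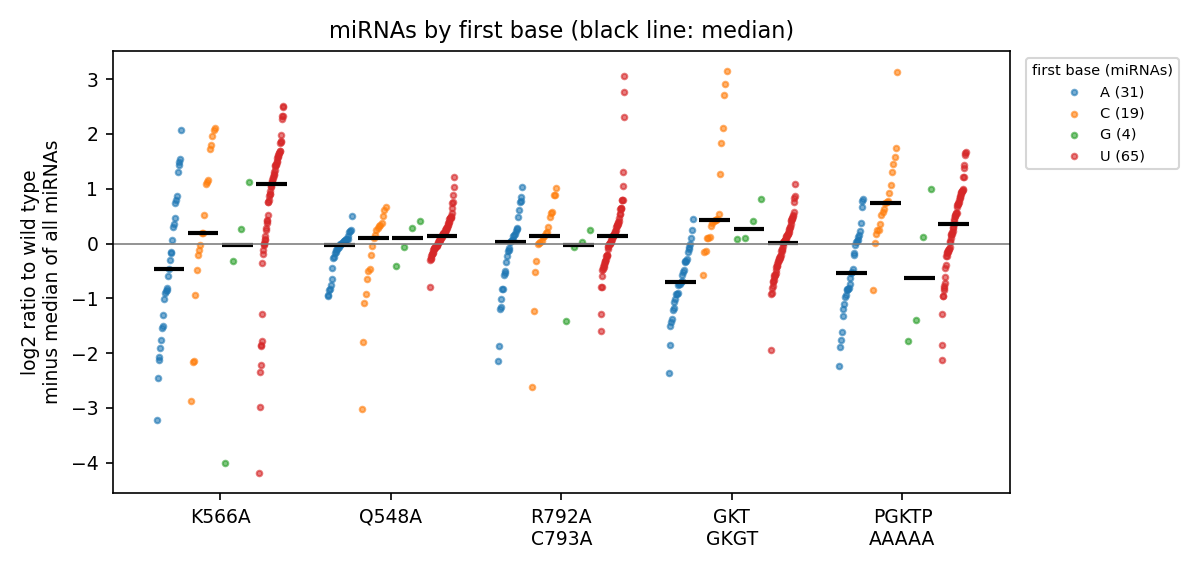
log2 ratio to wild type, minus the median of all tested miRNAs, for miRNAs grouped by first base, with 1 point per miRNA and black lines at medians. The U-first median lies at 1.09 in K566A, and the A-first median at -0.70 in GKT_GKGT and -0.54 in PGKTP_AAAAA.

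Q548A was closest to wild type, with a Spearman correlation of 0.97 across miRNAs, 6 miRNAs higher and 15 lower (4 and 22 with median-of-ratios scaling). Over the 5 mutants the correlations with wild type had the same order as the library totals. These totals were 99.9% of wild type in Q548A, 59.1% in R792A_C793A, 52.4% in GKT_GKGT, 26.3% in PGKTP_AAAAA and 15.7% in K566A. Whether depth gave that order was not tested. Among miRNAs of at least 100 CPM, miR-673-3p (1.72) and miR-423-5p (1.10) rose; miR-106b-3p (-2.95), miR-151-3p (-1.72), miR-666-5p (-1.21), miR-296-3p (-1.21) and miR-196a-1-3p (-1.14) fell. The 5p arm of miR-106b (in an intron of Mcm7) went from 3.91% to 29.5% of the hairpin. Other minor arms rose in miR-325 (2.46), miR-673 (1.96), miR-151 (1.96, in an intron of Ptk2) and miR-700 (1.82), and fell in miR-101a (at least 5.91-fold, exact limit 3.97), miR-3097 (-2.48), miR-142 (-2.23), miR-542 (-2.07) and miR-7a-1 (-2.07). Minor-arm share was higher in 15 hairpins and lower in 22, and the median change was -0.22 (-0.35 to -0.15). Within hairpins, with the same limit of more than 3 counts in at least 1 library for both arms, C-first arms lost to U-first arms (-0.73, -1.06 to -0.41, in 39 of 45), as did A-first arms (-0.82, -1.04 to -0.44, in 31 of 39). Set directly against each other mutant, the A-first over U-first interval included 0, as with R792A_C793A (-0.29, -0.86 to 0.11). The C-first over U-first median was lower in Q548A, with each interval apart from 0, except against K566A in hairpins with 1 copy. Of the lists, U-first miRNAs (0.15, percentile 99.8), the Sfmbt2 cluster (0.31, percentile 99.7, with miR-467e-5p at 0.67) and miR-17-92 with paralogs (0.22, percentile 98.9) lay above the random range, and the other 14 lay between percentiles 11.4 and 92.3. With the added first bases 6 of 47 C-first miRNAs fell and 0 rose (percentile 0.04), and 11 fell with median-of-ratios scaling. The 19 C-first miRNAs fixed before the values were seen lay on the other side, 0.10 above the median of all (percentile 88.4). U-first miRNAs then had a median 0.13 above that of all (percentile 99.9), with A-first at percentile 23.8 and G-first at 6.54.

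In R792A_C793A, among miRNAs of at least 100 CPM, miR-30e-5p (2.74), miR-674-3p (1.71), miR-200a-5p (1.52), miR-196a-1-3p (1.49) and miR-30d-5p (1.48) rose most, and miR-106b-3p (-2.20), miR-370-3p (-2.12), miR-130b-5p (-1.72), miR-423-3p (-1.71) and miR-294-5p (-1.44) fell most. The 3p arm of miR-423, in an intron of Nsrp1, went from 63.4% to 18.4% of the hairpin. The other large falls in minor-arm share were in miR-3091 (-5.40), miR-3097 (-3.50), miR-877 (-3.29) and miR-154 (-2.83), and the rises were in miR-1197 (at least 17.8-fold, exact limit 11.7), miR-326 (4.38), miR-598 (3.78), miR-760 (3.59) and miR-1249 (3.58). In this library 33 hairpins rose and 48 fell, with a median change of 0.01 (-0.19 to 0.21), and -0.19 (-0.35 to -0.02) against wild type thinned to its total, or -0.12 (-0.26 to 0.12) to the median-of-ratios size. Markers of differentiated tissues (0.58, percentile 99.2; miR-9-5p 1.23, miR-126-3p 1.06) lay above the random range and the Dlk1-Dio3 cluster (-0.35, percentile 0.22) below it; the other 15 lists lay between percentiles 6.80 and 94.0. With the added first bases the 19 G-first miRNAs had 4 higher and 4 lower (percentile 1.12), or 0 and 5 with median-of-ratios scaling (percentile 52.4 for the 4 fixed before), while A-first miRNAs lay at percentile 43.2, C-first at 93.2 and U-first at 85.1. The Spearman correlation with wild type was 0.93. In R792A_C793A 53 miRNAs rose and 23 fell, which median-of-ratios scaling turned to 19 and 45. Over the 5 mutants 23 of 85 list medians lay outside the central 95% of random lists, against 4.25 by chance if list members were independent. Members of a cluster or family are not, some lists share members, and all 5 comparisons share 1 wild-type library. The 2 counts therefore do not measure an excess over chance.

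**Figure D4:**
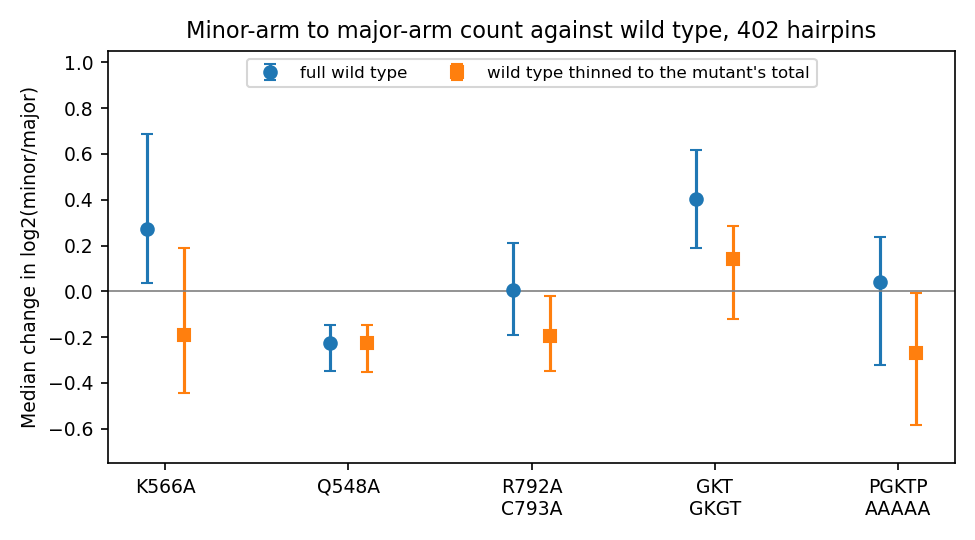
Median change in log2(minor/major) against wild type over 402 hairpins, with 95% order-statistic intervals, using full wild-type counts (circles) and wild-type counts thinned to each mutant's total (squares). The Q548A median lies at -0.22 in full wild type, and the K566A median moves from 0.27 to -0.19.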

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

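The values here come from the empty control, which enters the comparisons of a mutant with wild type only where its counts are subtracted as an alternative, and the test of them was written before its result was seen. In this library 146 miRNAs had more than the 3 counts that a count of 0 allows. miR-409-3p had 246 counts, miR-92a-3p 83, miR-27b-3p 54 and miR-203-3p, known from skin, 26. Against a mixture of the 6 Ago2 libraries fitted to the empty control, 186.5, 44.3, 19.3 and 0.466 counts were expected of these.

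The empty control had the miRNA profile of the Ago2 libraries, with 65.6% of its counts in miR-292-5p. Reads carried over from the Ago2 libraries would give its counts within counting error, but 86.8% (80.3 to 91.4) of 144 miRNAs lay inside the 99% Poisson interval of the fitted mixture, fewer than the 95% set in advance. Outside the interval 9 miRNAs lay above and 10 below. Carry-over with counting error alone is therefore argued against as the whole source. The interval leaves out any spread beyond counting error, so carry-over with such spread stays open. The fitted mixture was 81.2% Q548A, 9.78% PGKTP_AAAAA and 5.09% R792A_C793A. These shares add to the whole by construction, so they do not measure how much was carried over. The counts of 13 miRNAs beyond what the mixture gives were 0.811% of the library. Carry-over may therefore still account for most of the counts, as may another source with a profile like that of the Ago2 libraries. let-7b-5p (20 counts, 0.183 expected) and miR-100-5p (8 counts, 0.226 expected) were among those in excess, and RNA that binds without Flag-Ago2 stays open, since 1 library cannot separate these sources.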

How the results depend on the processing

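The thinned wild types, the count limit on arms, the total without miR-292-5p, the arm shifts by first base and their settings were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out and no other split of the samples could be made. The C-first over A-first shift ranged from 2.51 to 3.07 over the settings in GKT_GKGT and from 1.71 to 2.41 in PGKTP_AAAAA. With the scaled empty control subtracted the lower limits of these 2 intervals were 0; with every other setting they lay above it. In 2 of the 3 mutants whose interval includes 0 its sign changed, while Q548A stayed above 0: K566A was at -0.011 with at least 10 minor-arm counts, and R792A_C793A at -0.11 with the scaled empty control subtracted and -0.22 without hairpins of several copies. Of 1986 values of single miRNAs recomputed 427 stayed within their counting interval, 1546 moved and 13 reversed, and of 150 values of single hairpins 26 moved and 8 reversed. Of 120 counts of miRNAs 62 moved by more than 1.5 times, as did 25 of 80 counts of hairpins. Of 63 arm asymmetry medians 50 stayed, 10 moved and 3 reversed. Of 430 list medians 2 moved, but they are relative to the median of all miRNAs, so rescaling could not move them. Depth limits what can be seen of minor arms, and K566A has 15.7% of the wild-type total. By median-of-ratios size PGKTP_AAAAA is smaller, at 0.176 of wild type against 0.294 in K566A. Where no cause is named, the cause was not tested.

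Against thinned wild type the median change in log2(minor/major) reversed to -0.19 in K566A and moved to -0.19 in R792A_C793A and 0.14 in GKT_GKGT. Thinned to the median-of-ratios size it reversed to -0.076 in K566A and moved to 0.15 in GKT_GKGT and -0.57 in PGKTP_AAAAA. In PGKTP_AAAAA it was -0.27 against thinned wild type, with an interval below 0 (-0.59 to -0.01), 0.49 with a pseudocount of 5 and -0.35 with at least 10 minor-arm counts in both libraries. For GKT_GKGT against PGKTP_AAAAA it reversed to -0.049 with a pseudocount of 5. Subtraction of the empty control scaled to equal totals removes nearly every count of a miRNA that has the same share in both, and by this construction the medians became 0 in K566A, Q548A, GKT_GKGT and GKT_GKGT against PGKTP_AAAAA. Pearson correlations of log2(CPM + 1) with wild type were 0.77 in K566A, 0.98 in Q548A, 0.96 in R792A_C793A, 0.94 in GKT_GKGT and 0.92 in PGKTP_AAAAA, and Spearman correlations at 100 CPM or more were 0.66 in K566A and 0.88 in GKT_GKGT.

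An odds ratio threshold of 4 gave hairpins with a higher minor-arm share as 45 in K566A, 1 in Q548A, 12 in R792A_C793A, 39 in GKT_GKGT and 14 in PGKTP_AAAAA. For hairpins with a lower minor-arm share it was 37 in K566A, 1 in Q548A, 8 in R792A_C793A, 25 in GKT_GKGT and 28 in PGKTP_AAAAA. Without the interval the hairpins with a higher minor-arm share were 158 in K566A, 53 in Q548A, 93 in R792A_C793A, 142 in GKT_GKGT and 121 in PGKTP_AAAAA. For hairpins with a lower minor-arm share it was 121 in K566A, 79 in Q548A, 98 in R792A_C793A, 87 in GKT_GKGT and 128 in PGKTP_AAAAA. Median-of-ratios scaling gave higher miRNAs as 105 in K566A, 19 in R792A_C793A and 50 in PGKTP_AAAAA. Lower miRNAs then numbered 107 in K566A, 45 in R792A_C793A, 25 in GKT_GKGT and 63 in PGKTP_AAAAA. TMM scaling gave higher miRNAs as 102 in K566A, 20 in R792A_C793A and 45 in PGKTP_AAAAA. The lower miRNAs were 110 in K566A, 43 in R792A_C793A, 25 in GKT_GKGT and 73 in PGKTP_AAAAA. A 4-fold threshold gave higher miRNAs as 96 in K566A, 0 in Q548A, 6 in R792A_C793A, 19 in GKT_GKGT and 6 in PGKTP_AAAAA. For lower miRNAs it was 42 in K566A, 1 in Q548A, 5 in R792A_C793A, 9 in GKT_GKGT and 41 in PGKTP_AAAAA. No filter on low values gave higher miRNAs as 272 in K566A, 86 in R792A_C793A, 75 in GKT_GKGT and 38 in PGKTP_AAAAA. Lower miRNAs then numbered 115 in K566A, 31 in Q548A, 39 in R792A_C793A, 73 in GKT_GKGT and 198 in PGKTP_AAAAA. A minimum of 100 CPM gave higher miRNAs as 76 in K566A, 2 in Q548A, 23 in R792A_C793A, 20 in GKT_GKGT and 12 in PGKTP_AAAAA. The lower miRNAs were 32 in K566A, 5 in Q548A, 9 in R792A_C793A, 18 in GKT_GKGT and 42 in PGKTP_AAAAA. The total without miR-292-5p, chosen after seeing the data, gave higher miRNAs as 86 in K566A and 28 in R792A_C793A. For lower miRNAs it was 117 in K566A, 36 in R792A_C793A and 24 in GKT_GKGT. The total without the miR-290 cluster gave lower miRNAs as 106 in K566A and 37 in R792A_C793A. For higher miRNAs it was 25 in R792A_C793A. Subtraction of the scaled empty control gave lower miRNAs as 123 in K566A, 36 in Q548A, 69 in R792A_C793A and 110 in GKT_GKGT. For higher miRNAs it was 69 in Q548A. An odds ratio threshold of 1.5 gave hairpins with a higher minor-arm share as 37 in Q548A, 55 in R792A_C793A and 43 in PGKTP_AAAAA. For hairpins with a lower minor-arm share it was 67 in Q548A and 74 in R792A_C793A. A 1.5-fold threshold gave higher miRNAs as 25 in Q548A, 113 in R792A_C793A and 45 in PGKTP_AAAAA. Lower miRNAs then numbered 44 in Q548A, 49 in R792A_C793A and 92 in GKT_GKGT.

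A single miRNA counts as reversed only if it was called higher or lower and then changed sign. Single values that reversed did so with the scaled empty control subtracted, except miR-150-5p in K566A (-0.056, total without miR-292-5p). In K566A they were let-7d-3p (-0.83), let-7a-5p (-0.66), let-7d-5p (-0.52), miR-183-3p (-2.15), miR-467a-5p (-1.53), miR-203-3p (-0.66) and the hairpins miR-598 (-0.49) and miR-877 (11.18). In Q548A they were miR-196a-1-3p (0.71) and the hairpin miR-542 (1.06), and in R792A_C793A miR-9-5p (-0.43) and the hairpins miR-598 (-2.20), miR-877 (4.33), and hairpin miR-423 R792A_C793A stood at 23.31. The value of hairpin miR-291a GKT_GKGT was -19.98. In PGKTP_AAAAA they were miR-673-3p, miR-409-5p, miR-433-3p and miR-143-3p (0.99 each) and the hairpin miR-205 (7.06). Values of this size come from arms left at 0 by the subtraction.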

Other observations

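The tests of less abundant hairpins, of the range of the GC slope, of variation between libraries and of background in K566A were chosen after the results were seen. Leaving out miR-292-5p, C-first miRNAs took 12.2% of wild-type counts, 24.9% in GKT_GKGT and 20.1% in PGKTP_AAAAA, and A-first miRNAs took 52.8%, 35.6% and 40.04%. G-first miRNAs took 8.92% in wild type and 2.21% in K566A, and U-first miRNAs 22.2% and 30.6%. With miR-292-5p, itself A-first, included, A-first miRNAs took 82.8% in wild type, 81.0% in GKT_GKGT and 81.7% in PGKTP_AAAAA, and C-first miRNAs 4.44%, 7.36% and 6.12%. Of hairpins chosen after their values were seen, the 5p arm of miR-199a held 94.97% of the hairpin in PGKTP_AAAAA against 56.5% in wild type. The 3p arm of let-7d held 80.1% against 57.4%.

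C-first arms gained on G-first arms in 10 hairpins by 0.91 (0.09 to 1.66) in GKT_GKGT and 1.32 (0.19 to 3.42) in PGKTP_AAAAA. The medians were higher in R792A_C793A (1.64, -0.38 to 2.66) and K566A (1.35, -2.93 to 4.56), with intervals that include 0. With the count limit on arms, direct differences of K566A, Q548A and R792A_C793A from these mutants had intervals that include 0. The exception was Q548A against PGKTP_AAAAA (-1.03, -3.98 to -0.25). U-first arms gained on G-first arms by 0.56 (0.22 to 1.25) in Q548A, in 14 of 18 hairpins with both arms above 3 counts in at least 1 library, and by 0.64 (-0.31 to 1.32) in the 15 with 1 copy, an interval that includes 0.

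C-first arms gained on A-first arms in GKT_GKGT and PGKTP_AAAAA. In the 10 less abundant of 20 hairpins the shift was 3.09 (1.10 to 4.13) in GKT_GKGT, above the bound of 1, which argues against a few abundant hairpins. In PGKTP_AAAAA it was 2.23 (0.92 to 3.73), an interval that reaches below that bound but lies above 0. The C-first arm gained there in 19 of 20 hairpins, but that count is the pattern itself and not a separate test. The less abundant hairpins of that library thus showed a gain, while a larger part from abundant hairpins stays open. Random loss of counts at lower depth is argued against, since thinned against full wild type shifted by 0.00571 and 0.0369. Thinning keeps each arm's expected share, so this covers no other effect of depth. A linear GC trend is argued against too. It was fitted on the 189 of 402 hairpins with both sequences, which include all 22. After it the shift was 2.59 (1.89 to 3.25) in GKT_GKGT and 2.01 (1.08 to 2.74) in PGKTP_AAAAA. The interval stayed above 1 over the bootstrap range of the slope, which in PGKTP_AAAAA (-0.039 to 0.017 per percent) includes 0. Variation between single libraries stays open: the highest shift in the other 3 mutants was 0.438 (0.62 with the count limit on arms), but each genotype has 1 library. The loop changes that the labels name stay open and untested, and replicate libraries of each genotype would be needed to separate them from such variation.

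U-first miRNAs lay above the median in K566A. Random loss of counts at lower depth is argued against by a value of -0.000272 for thinned against full wild type. Thinning keeps each miRNA's expected share, so this covers no other effect of depth. Background with the profile of the empty control is argued against, since miR-292-5p took 65.6% there and 21.7% in K566A. Carry-over may account for most counts of that control, so background of another profile is not covered and stays open. GC content stays open: after a linear term the U-first median was 0.69, at percentile 97.6 of random lists and on their upper limit, so GC content could not be separated from first base, and within hairpins no gain of U-first arms was detectable (C-first over U-first -0.099, -0.83 to 0.70).

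Across 218 of 338 miRNAs with a sequence, GC content and the K566A log2 ratio had a Spearman correlation of -0.28 (-0.41 to -0.13), a check that is void because 64.5% had a value. On the same miRNAs, and with the same limit, the correlation was -0.43 (-0.54 to -0.30) in Q548A and -0.27 (-0.40 to -0.12) in R792A_C793A. In GKT_GKGT it was 0.13 (0.002 to 0.25) and in PGKTP_AAAAA 0.03 (-0.10 to 0.17). End stability and log2(5p/3p) had a Spearman correlation of -0.43 (-0.54 to -0.30) in wild type, with a K566A difference of 0.093 (0.040 to 0.147), and both are void because 47.0% of hairpins had a value.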
